A study of Mus musculus with 4 samples.

How the data were processed

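RNA sequencing of Py8119 mouse mammary tumour cells was analysed from the authors' deposited table of gene values. The labels assign 2 libraries to the control and 2 to Mtss1 overexpression, and these were the groups compared. Per the labels' protocols, RNA was extracted with Trizol and sequenced as paired ends of 150 bases. Per the submitters' processing notes, FastQC 0.11.2, STAR, RSEM and the mouse genome build mm10 were used, with no roles or settings given. The deposited values are CPM, read counts scaled to 1000000, an assignment made from the values themselves. The 4 columns sum to between 982877 and 1016225, and the product of the sums, each divided by 1000000, is 1, the form that TMM-type scaling factors leave. What scaled the values is not given in the sources used here.

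The values of a library are multiples of a constant step, which is the CPM of 1 read. Dividing by the step gave values that were whole within 0.005 read for 79.6% to 80.5% of the nonzero entries, and multiples of a hundredth of a read within 0.001 read for 100% of them, as RSEM's expected counts would be. Recovered totals were 20617788, 22081639, 15594209 and 16656638 reads for control 1, control 2, overexpression 1 and overexpression 2. A floor of 3 reads corresponds to 0.138 to 0.189 CPM. The deposited unit was treated as normalized, so no test for raw counts was used as the main test. A count model had been named as the main test for raw counts before the data were examined, and limma, its stated replacement for normalized values, took its place.

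The table holds 50600 genes with Ensembl identifiers and symbols. Coordinates were taken from the GENCODE M21 annotation of the same build, which matched 50376 identifiers. Chromosome names in the table and the annotation were the same for 35621 of 35623 genes compared. A symbol on several rows was read from the row with the highest mean.

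Replicates were compared before they were averaged. Over genes with at least 50 reads, the median chi-square between the libraries of a group was 2.01 times the Poisson value for the control and 1.81 times for overexpression, so they differed by more than sampling noise and were kept as 2 replicates each. Between groups the ratio was 26.8 to 28.4.

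Expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-dependent prior) on log2(CPM + 1), for genes with at least 1 CPM in at least 2 libraries. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The pseudocount of 1 means that fold changes are on the log2(CPM + 1) scale and understate the change of low genes. Residual degrees of freedom were 2 per gene, and the prior added 20.0. Tables of CPM give means and standard deviations over n = 2. Reads of overlapping genes, close paralogs and nuclear copies of mitochondrial genes could have been divided among them by the upstream counting.

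Before the data were examined, 21 gene lists were written from general knowledge, together with the groups, the tests, the alternatives and the rule for naming genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 18 lists with at least 5 tested members. With an estimated correlation camera rests on the 2 residual degrees of freedom, so few lists could pass whatever their correlation. Fry tests whether the members of a list move, on balance, in a common direction and does not compare them with other genes. The rule names Mtss1 and Rela, the 8 genes with the largest fitted change in each direction (adjusted p under 0.05, mean of at least 1, no overlap of the groups, predicted genes and pseudogenes passed over), and the members with the largest changes past the threshold in each list, up to 4 for NF-kB target genes and up to 3 for the others. Genes outside the rule are marked as named after their values were seen, except list members under the filter, which are named without values. Some list members that meet the rule are not reported here.

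The steps were tested on simulated data with the real means and depths and known changes. In a simulation of this comparison with 12408 genes tested, 58.3% of genes changed 1.25-fold, 70.0% of those changed 1.5-fold, 89.4% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 10 of 165 calls were unchanged genes. Camera called 2 of 18 lists, and 0 lists without a changed member. Genes were simulated independently and few were changed, whereas 66.1% of the tested genes were called in the data. The simulation therefore does not show how camera or the share of false calls behaves with correlated genes or so wide a difference.

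The alternatives were limma-voom on the recovered expected counts, median-of-ratios scaling, scaling by library size, no filter, at least 1 CPM in all libraries, the replicate number as a block, pseudocounts of 0.1 and 5, an adjusted p of 0.01, and leaving out each library in turn. After the data were examined, tests of 961 gene ontology terms carried by the deposited table, of a 22-gene list of YAP and TEAD targets with and without the members named here, and of nuclear respiratory chain genes were added. Nuclear copies of mitochondrial mRNAs were found with blastn 2.17.0 among annotated transcripts (at least 90% identity over at least 100 bases). Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.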

Results

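Gene expression was measured by RNA sequencing in Py8119, a mouse mammary tumour cell line of C57BL/6 origin that the labels describe as mesenchymal-like. A control population and a population overexpressing Mtss1 were sequenced, with 2 libraries each (control 1 and 2, overexpression 1 and 2), from total RNA read as paired ends. Mtss1 encodes a scaffold protein with a membrane-bending I-BAR domain and an actin-binding WH2 domain. Values were in CPM, read counts scaled to a library of 1000000, for 50600 genes. The read steps in the values gave recovered totals of 20617788 and 22081639 reads for control 1 and 2 and of 15594209 and 16656638 reads for overexpression 1 and 2. Between 12096 and 12288 genes per library reached 1 CPM. Across genes, the lowest Pearson correlation of log2(CPM + 1) between the libraries of a group was 0.997 and the highest between groups was 0.957; genes are not independent replicates. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

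The overexpressed gene was examined before all others. Mtss1 (ENSMUSG00000022353) read 54.5 and 50.5 CPM in control 1 and 2 and 118 and 119 CPM in overexpression 1 and 2. Its mean rose from 52.5 ± 2.82 to 119 ± 0.679 CPM (SD, n = 2), which is 2.26-fold, with a log2 fold change of 1.16 ± 0.05 (SE) and a limma adjusted p of 4.8e-15. The gene lies on the minus strand of chromosome 15 from 58941234 to 59082005 (mm10), and reads of the introduced and the native copy were not told apart. The series title places the comparison in work on Mtss1, tumour-initiating mammary cells and the turnover of the p65 protein. Rela, which encodes p65 (ENSMUSG00000024927, chromosome 19, 5637483 to 5648130), read 92.0 and 94.6 CPM in the control libraries and 91.8 and 86.3 CPM with overexpression. Its log2 fold change of -0.07 ± 0.05 (SE) did not pass the test (limma adjusted p = 0.22). These values measure RNA and say nothing about the amount of p65 protein.

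Differences between the populations extended over a large part of the transcriptome. Of 12510 genes tested, 3991 were higher and 4282 lower with Mtss1 overexpression at a limma adjusted p under 0.05, together 66.1%. A change of at least 2-fold on the log2(CPM + 1) scale was reached by 555 of the higher and 479 of the lower genes, and one of at least 4-fold by 146 and 48. The 2 groups of libraries did not overlap for 81.6% of the tested genes, where chance gives 33.3%. The median log2 fold change over all tested genes was -0.01. The counts at 2-fold depend on how low genes are treated. With at least 1 CPM required in all libraries 318 genes were higher at 2-fold, and with a pseudocount of 5 the counts were 235 higher and 205 lower, whereas limma-voom gave 788 higher and 722 lower. Leaving out overexpression 1 or overexpression 2 gave 360 and 357 genes higher at 2-fold. In each case 204 of the 555 genes then reached 1 CPM in fewer than 2 libraries and were not tested.

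**Figure D1:**
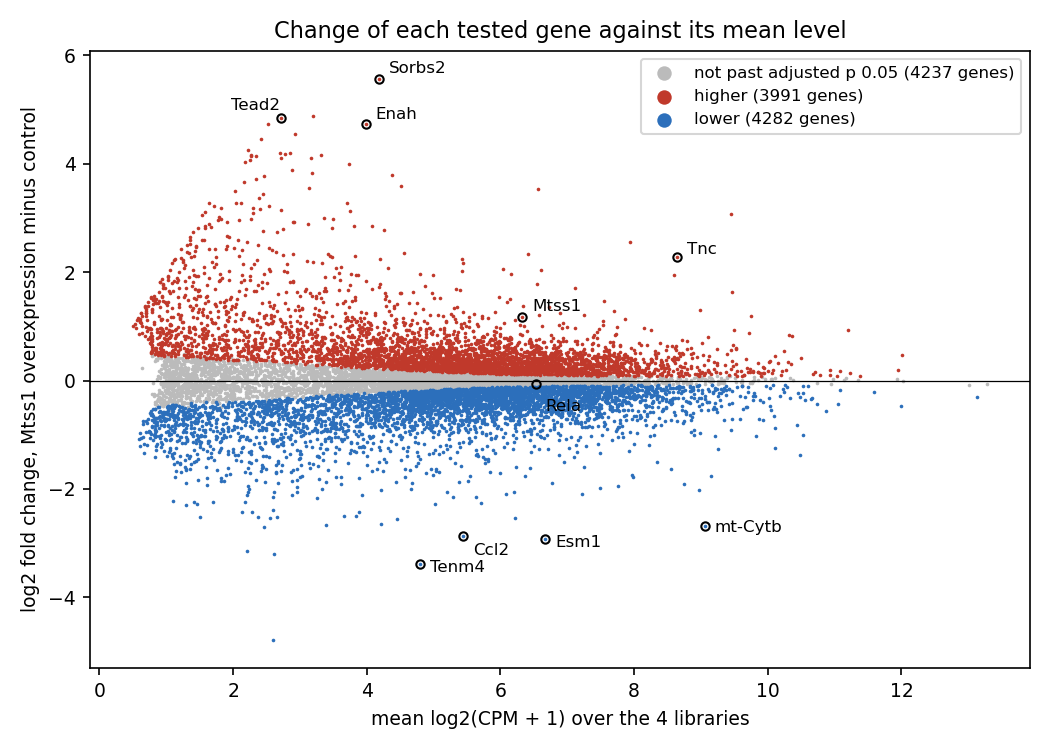
Each point is a tested gene. The x axis gives its mean log2(CPM + 1) over the 4 libraries and the y axis its log2 fold change, overexpression minus control. Red points (3991 genes) were higher and blue points (4282 genes) lower at a limma adjusted p under 0.05, and circles mark genes named in the text, among them Mtss1 at 1.16 and Rela at -0.07.

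The largest rises were in genes that were close to silent in the control. Sorbs2, an adaptor protein of actin stress fibres, rose from 1.65 ± 0.397 to 124 ± 6.81 CPM (SD, n = 2), a log2 fold change of 5.57 ± 0.11 (SE). Enah, an Ena/VASP protein that promotes actin filament elongation, rose from 2.10 ± 0.545 to 80.3 ± 2.78 CPM (4.72 ± 0.11). The transcription factor Tead2, a DNA-binding partner of YAP, went from 0.236 to 34.3 CPM (4.84 ± 0.14), and the extracellular matrix glycoprotein Efemp2 from 0.694 to 48.7 CPM (4.88 ± 0.14). The transporter gene Slco5a1 (0.117 to 28.6 CPM), the microtubule-associated kinase Dclk2 (0.602 to 35.7 CPM), the membrane skeleton protein Epb41l3 (0.144 to 24.3 CPM) and Bend4 (0.072 to 19.3 CPM) completed the 8 largest rises. Among the 8 largest falls, the teneurin Tenm4 dropped from 89.0 ± 3.79 to 7.60 ± 0.481 CPM (log2 fold change -3.39 ± 0.08), Esm1, a secreted proteoglycan, from 279 ± 2.68 to 35.9 ± 1.66 CPM (-2.92 ± 0.05), and the monocyte-attracting chemokine Ccl2 from 116 ± 0.374 to 15.1 ± 1.94 CPM (-2.87 ± 0.07). Megf10 (17.6 to 1.01 CPM), the protein kinase C gene Prkcb (12.8 to 0.576 CPM), Foxred2 (13.1 to 1.19 CPM), the phosphodiesterase gene Pde1b (25.4 to 3.22 CPM) and mt-Cytb of the mitochondrial genome (1351 to 210 CPM) were the others. The limma adjusted p was 1.5e-12 or lower for these 16 genes, with no overlap between the groups. In mm10, Sorbs2 lies on chromosome 8 from 45507788 to 45827906, Enah on chromosome 1 from 181896384 to 182019990, Tenm4 on chromosome 7 from 96171246 to 96911093, Esm1 on chromosome 13 from 113209659 to 113218098 and Ccl2 on chromosome 11 from 82035571 to 82037453. Nuclear copies of mitochondrial DNA can share reads with mt-Cytb. The 1 annotated copy found for it read at most 0.23 CPM in any library, and adding it left the log2 fold change at -2.69.

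NF-kB target genes moved in both directions. Of 36 tested members, 16 fell, 11 rose and 9 did not pass the test. The chemokine genes Ccl2 (log2 fold change -2.87), Ccl20 (-2.52 ± 0.15, 14.1 to 1.66 CPM) and Ccl7 (-2.10 ± 0.16, 8.59 to 1.22 CPM) fell most, followed by the receptor gene Tlr2 (-1.49 ± 0.06, 93.6 to 32.6 CPM). Among the members that rose, named after their values were seen, were Gadd45b (1.21 ± 0.07), the cytokine gene Il6 (0.90 ± 0.16, 2.81 to 6.09 CPM), and Tnfaip3 (0.53 ± 0.06) and Nfkbia (0.26 ± 0.05), which encode feedback inhibitors of the pathway. For Il6, a low gene, the log2 fold change ran from 0.51 to 1.13 over 12 alternative settings. The list's median log2 fold change was -0.08 and its mean -0.27. As a set it did not pass camera (adjusted p = 0.28, and 0.62 with an estimated correlation). It passed in 2 of 12 alternative settings, 1 of them without control 2 (camera adjusted p = 0.032), in a range of 0.032 to 0.32. Icam1, Cxcl2, Tnf and Il1b were among the members under the expression filter.

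**Figure D2:**
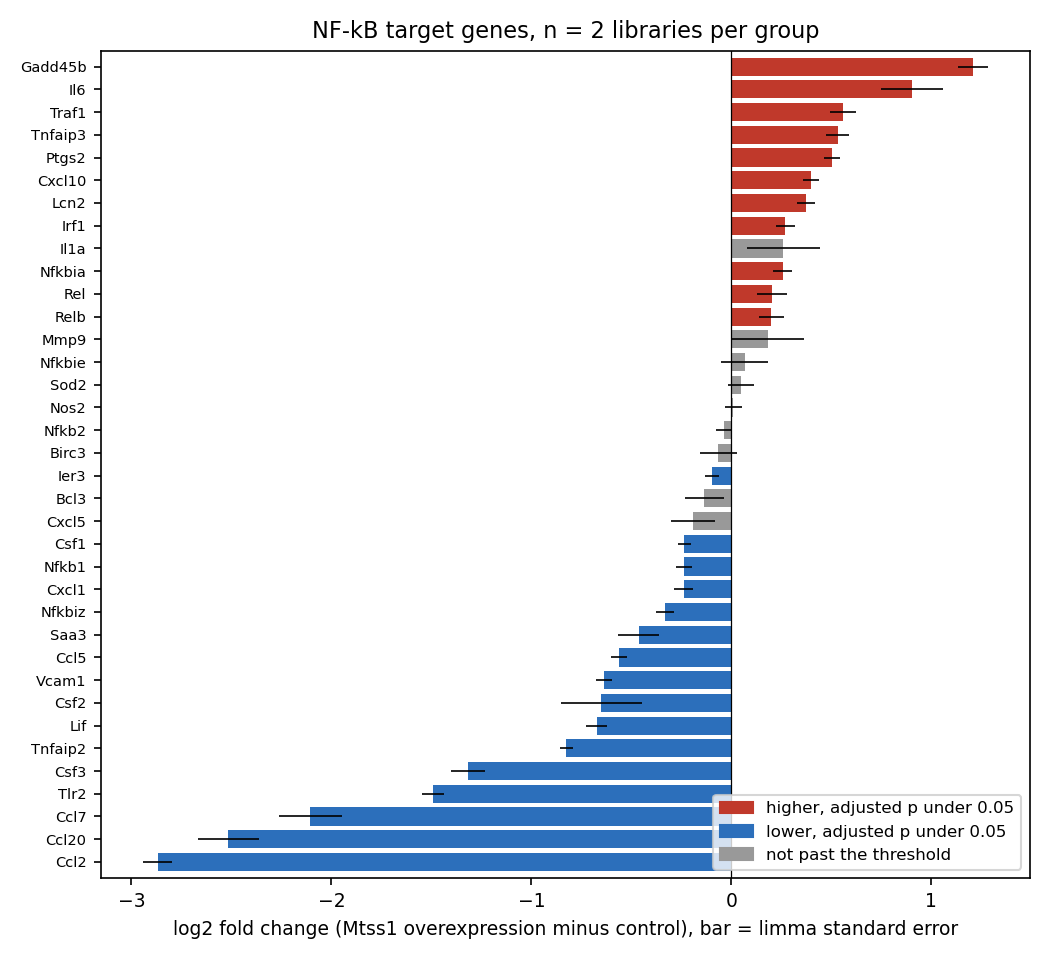
Bars give the log2 fold change (overexpression minus control) of each of the 36 tested NF-kB target genes, with the limma standard error, n = 2 libraries per group. The 16 members that fell (blue) run to -2.87 for Ccl2 and the 11 that rose (red) to 1.21 for Gadd45b, and 9 (grey) did not pass an adjusted p of 0.05.

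Genes for NF-kB signalling components were more often lower than higher. Of 38 tested, 17 fell, 8 rose and 13, Rela among them, did not pass. The suppressor of cytokine signalling Socs1 fell from 10.5 to 4.66 CPM (log2 fold change -1.03 ± 0.13) and the receptor-proximal kinase Irak4 from 29.8 to 16.9 CPM (-0.80 ± 0.10), while the interleukin 1 receptor gene Il1r1 rose from 2.28 to 4.55 CPM (0.75 ± 0.16). The median was -0.10 and the set did not pass camera (adjusted p = 0.21, and 0.62 with an estimated correlation). Of 38 genes for proteasome subunits and ubiquitin, 12 rose, 12 fell and 14 did not pass. Psmd11 rose by 0.59 ± 0.04 and Psmc4 fell by 0.52 ± 0.05. This list had a median of 0.0027 (-0.01 to 0.04 over 12 alternative settings) and a mean of -0.0039, with opposite signs, and a camera adjusted p of 0.87.

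Markers used for mammary stem and tumour-initiating cells moved in both directions. Of 17 tested, 7 fell, 5 rose and 5 did not pass. The transcription factor genes Klf4 (log2 fold change -1.39 ± 0.06, 80.8 to 30.3 CPM), Sox2 (-1.11 ± 0.12, 17.2 to 7.49 CPM) and Sox9 (-0.92 ± 0.05, 119 to 62.9 CPM) fell most. The surface marker genes Procr (0.66 ± 0.07), Ly6a (0.59 ± 0.05), Itga6 (0.56 ± 0.04) and Cd44 (0.33 ± 0.04, 541 to 680 CPM), named after their values were seen, rose. The median was 0.06 (-0.02 to 0.14 over 12 alternative settings, so its sign is not settled), the mean -0.12 and the direction given by camera downward, with a camera adjusted p of 0.87 and a fry adjusted p of 0.0094, also downward. Aldh1a1, Prom1, Itgb3 and Lgr5 lay under the expression filter.

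Mesenchymal and EMT genes split as well, with 10 of 28 higher, 14 lower and 4 not past the test. The matricellular gene Ctgf rose from 3.94 to 23.2 CPM (log2 fold change 2.29 ± 0.12) and the growth factor gene Tgfb2 from 3.74 to 20.2 CPM (2.16 ± 0.12). The collagen receptor gene Ddr2 (-1.77 ± 0.04, 467 to 136 CPM) and S100a4 (-1.51 ± 0.04, 547 to 192 CPM), named after their values were seen, fell. Vim, the gene of the intermediate filament vimentin, also named afterwards, read 4156 ± 206 CPM in control and 4127 ± 98.5 CPM with overexpression (log2 fold change -0.01 ± 0.04, and between -0.06 and 0.04 over 12 alternative settings). The list's median was -0.13 and its mean 0.04; camera pointed down and fry up, and the camera adjusted p was 0.87. Of 9 luminal epithelial genes that passed the filter 5 rose, including the transcription factor genes Ehf (0.233 to 8.52 CPM, 2.96 ± 0.18) and Gata3 (0.91 ± 0.06) and the receptor gene Erbb3 (1.38 ± 0.19). Another 3 fell, among them the keratin genes Krt8 (-0.67 ± 0.04) and Krt18 (-0.28 ± 0.04, both named after their values were seen), 1 did not pass, and the camera adjusted p was 0.78. Of the basal and myoepithelial genes 4 passed the filter: Egfr rose from 13.7 to 44.5 CPM (1.63 ± 0.09), Mylk (-1.55 ± 0.13) and Sfn (-0.73 ± 0.16) fell, and Apoe, named after its value was seen, did not pass, though it did without overexpression 1. Epcam and Cdh1 were under the filter in both groups.

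Extracellular matrix genes were mostly higher with Mtss1 overexpression. Of 34 tested, 25 rose, 7 fell and 2 did not pass, and adjusted over the list alone the counts were 25 and 8. Tenascin C (Tnc) rose from 180 ± 0.581 to 884 ± 10.2 CPM (log2 fold change 2.29 ± 0.03), the fibulin gene Fbln2 from 197 ± 14.0 to 761 ± 3.42 CPM (1.95 ± 0.04), and the collagen VI gene Col6a2 from 0.569 to 4.06 CPM (1.68 ± 0.19). Vcan (-1.59 ± 0.05) and Col1a2 (-1.23 ± 0.05), named after their values were seen, fell. The list's median was 0.51 (0.25 to 0.61 over 12 alternative settings) and it passed camera (adjusted p = 2.4e-05), but not with an estimated correlation (adjusted p = 0.62).

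Actin regulators and genes related to Mtss1 also leaned upward, with 21 of 42 higher, 11 lower and 10 not past the test. Besides Enah, the profilin gene Pfn2 rose from 6.29 to 48.9 CPM (2.77 ± 0.09) and Ptprd, a receptor phosphatase gene, from 1.18 to 11.4 CPM (2.51 ± 0.16). Flna, the filamin A gene, named after its value was seen, fell from 1503 to 816 CPM (-0.88 ± 0.03). The median was 0.10 and the mean 0.33, with a camera adjusted p of 0.016, and of 0.62 with an estimated correlation. Of 15 Hedgehog pathway genes, 7 fell, 4 rose and 4 did not pass. Gas1, a cell-surface co-receptor of Hedgehog ligands, fell from 179 to 30.0 CPM (-2.54 ± 0.05) and Foxl1 by 1.16 ± 0.14, while Gli1 rose from 0.492 to 2.48 CPM (1.23 ± 0.20). The camera adjusted p of that list was 0.38. Of 10 Wnt and Notch target genes, 5 rose, including Sfrp1 (1.11 ± 0.17) and Notch3 (1.08 ± 0.18), 4 fell, including Wisp1 (-0.84 ± 0.09), and 1 did not pass. Their camera adjusted p was 0.87, with a median of 0.17 and a downward direction in fry.

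**Figure D3:**
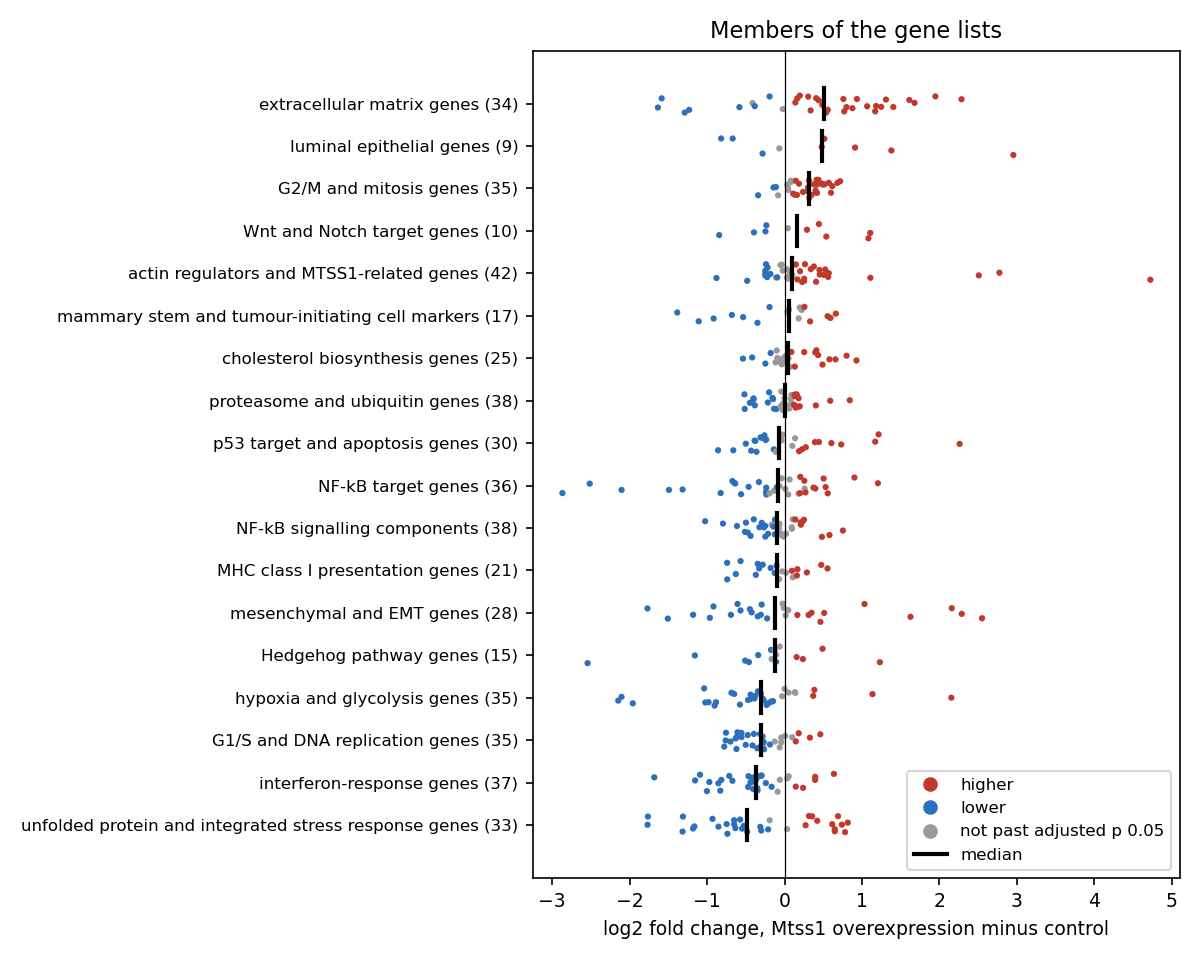
Each point is a tested member of a gene list, placed by its log2 fold change (overexpression minus control) with small vertical scatter, and the black bar is the list median. Numbers in brackets are tested members. Over these 18 lists, each with at least 5 tested members, the medians run from -0.48 for unfolded protein and integrated stress response genes to 0.51 for extracellular matrix genes.

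Cell cycle genes moved apart by phase. Of 35 G1/S and DNA replication genes, 24 fell, 4 rose and 7 did not pass. The replicative helicase genes Mcm2 (log2 fold change -0.78 ± 0.04, 288 to 167 CPM) and Mcm3 (-0.76 ± 0.04) and the flap endonuclease gene Fen1 (-0.76 ± 0.06) fell most among them. Of 35 G2/M and mitosis genes, 26 rose, 3 fell and 6 did not pass. Cdc20, an activator of the anaphase-promoting complex, rose from 76.9 to 127 CPM (0.72 ± 0.05), the spindle midzone gene Prc1 from 131 to 211 CPM (0.68 ± 0.04) and the phosphatase gene Cdc25c from 30.4 to 47.2 CPM (0.62 ± 0.07). The list medians were -0.31 and 0.32. Both lists passed camera (adjusted p = 1.4e-04 for G1/S and 4.3e-06 for G2/M), and neither did with an estimated correlation (adjusted p = 0.62 for both).

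Interferon-response genes were mostly lower. Of 37 tested, 28 fell, 5 rose and 4 did not pass. The mitochondrial nucleotide kinase gene Cmpk2 fell from 102 to 31.1 CPM (log2 fold change -1.68 ± 0.06), the antiviral GTPase gene Mx1 from 39.8 to 17.4 CPM (-1.16 ± 0.09) and the ubiquitin-like modifier gene Isg15 from 297 to 139 CPM (-1.09 ± 0.04). Rsad2, also interferon-induced and named after its value was seen, rose by 0.64 ± 0.04. The median was -0.36 and the list passed camera (adjusted p = 2.0e-06), but not with an estimated correlation (adjusted p = 0.62). Of 21 genes for MHC class I presentation, 11 fell, 6 rose and 4 did not pass. The class I transactivator gene Nlrc5 (-0.74 ± 0.04, 182 to 109 CPM), Tapbpl (-0.74 ± 0.13) and the immunoproteasome gene Psmb10 (-0.63 ± 0.09) fell most, and the camera adjusted p was 0.40.

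Hypoxia and glycolysis genes were likewise mostly lower, with 26 of 35 lower, 4 higher and 5 not past the test. The lactate transporter gene Slc16a3 fell from 103 ± 6.91 to 22.6 ± 0.0927 CPM (log2 fold change -2.15 ± 0.06) and Ankrd37 from 14.3 to 2.55 CPM (-2.11 ± 0.14). Hexokinase 2 (Hk2, -1.04 ± 0.04), Vegfa (-0.98 ± 0.06) and the glucose transporter gene Slc2a1 (-0.89 ± 0.04), named after their values were seen, fell too. Pfkfb3, which encodes an activator of glycolytic flux, rose from 2.34 to 13.7 CPM (2.15 ± 0.15). The median was -0.31 and the camera adjusted p 1.6e-05, and 0.62 with an estimated correlation.

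Of 33 genes of the unfolded protein and integrated stress responses, 20 fell, 11 rose and 2 did not pass, and adjusted over the list alone 21 were lower and 11 higher. Atf5 (log2 fold change -1.77 ± 0.06, 85.0 to 24.2 CPM), the cystathionine gamma-lyase gene Cth (-1.76 ± 0.05, 151 to 43.9 CPM) and the cystine transporter gene Slc7a11 (-1.32 ± 0.05, 137 to 54.6 CPM) fell most. Members named after their values were seen went both ways: Atf4 fell by 0.63 ± 0.03 and Trib3 by 0.93 ± 0.05, while Ddit3, a transcription factor gene downstream of Atf4 (0.78 ± 0.04, 131 to 226 CPM), and Hspa5 (0.82 ± 0.04, 986 to 1738 CPM) and Pdia6 (0.74 ± 0.03), a chaperone and a disulphide isomerase of the endoplasmic reticulum, rose. The list passed camera (adjusted p = 0.011), but not with an estimated correlation (adjusted p = 0.62). Of 25 cholesterol biosynthesis genes, 11 rose, 4 fell and 10 did not pass, with 10 higher when adjusted over the list alone. Hmgcs1 (0.93 ± 0.04, 221 to 420 CPM), Dhcr7 (0.80 ± 0.06) and Insig1 (0.66 ± 0.04) rose most. This list did not pass camera (adjusted p = 0.083) and passed in 4 of 12 alternative settings, among them without control 2 (0.010), without overexpression 1 (0.025) and with at least 1 CPM in all libraries (0.029), in a range of 0.010 to 0.11. Of 30 p53 target and apoptosis genes, 13 fell, 10 rose and 7 did not pass. Pmaip1 (0.069 to 4.20 CPM, 2.26 ± 0.20) and Perp (1.17 ± 0.17) rose. The list's median was -0.07, its mean 0.08 and its camera direction downward, with an adjusted p of 0.87.

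Markers of other cell types were scarce. Of 22 immune cell markers 2 passed the filter: Cd68, a lysosomal glycoprotein gene, rose from 18.6 ± 1.69 to 92.2 ± 0.374 CPM (log2 fold change 2.25 ± 0.07), and Lyz2, named after its value was seen, did not pass the test, though it did without control 2. Of 20 endothelial, pericyte and adipocyte markers 3 passed the filter. Fabp4 rose from 36.8 to 83.2 CPM (1.16 ± 0.06) and Des from 1.54 to 5.48 CPM (1.35 ± 0.16), and Vwf, also named afterwards, which did not pass over all genes, was lower when adjusted over the list alone. For every list not given its own count above, the counts adjusted over the list alone equalled those over all genes tested. Each of the 7 lists that passed camera with the preset correlation missed the threshold with an estimated correlation. That form rests on 2 residual degrees of freedom and could hardly pass any list, so these misses do not decide whether correlation explains the calls. The estimated correlation was 0.53 for interferon-response, 0.46 for hypoxia and glycolysis, 0.39 for G2/M and 0.20 for G1/S genes. These estimates lie far above the preset 0.01, so the preset may overstate the evidence for these lists. It was 0.022 for actin regulators and 0.0091 for the stress responses. For extracellular matrix genes it was -0.0059, below the preset, yet the camera p went from 5.4e-06 to 0.034. Fry, which does not compare a list with other genes, also called lists that camera did not: downward the stem cell markers (adjusted p = 0.0094), the NF-kB target genes, the Hedgehog pathway and MHC class I presentation (0.011 each) and the NF-kB signalling components (0.018), and upward the luminal epithelial genes (0.042) and cholesterol biosynthesis (0.049). It called the 7 lists that passed camera too. With 66.1% of all tested genes past the threshold, a fry call does not set a list apart from other genes.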

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

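The number of genes past the threshold lay between 3317 and 4362 for higher and between 3621 and 4337 for lower genes over the alternatives run. Median-of-ratios scaling and library size scaling shifted the median log2 fold change of all genes from -0.01 to -0.0011 and 0.02, and 49.8% and 52.9% of the calls were then higher, against 48.2%. The counts at 2-fold moved further. Requiring 1 CPM in all libraries left 318 higher genes, with 237 of the 555 not tested, a pseudocount of 5 left 235 higher and 205 lower, and limma-voom gave 788 higher and 722 lower. Without 1 library at a time the higher count ran from 357 to 594. With 1 library left in a group, that library is assumed to vary like the other group. The log2 fold change of Mtss1 stayed between 1.11 and 1.22, and that of Rela between -0.11 and -0.02, past the threshold in none of these settings. The NF-kB target list had medians of -0.10 to -0.056 without 1 library at a time, and it passed camera without control 2 (adjusted p = 0.032). It also passed with the replicate block (median -0.081, adjusted p = 0.034), and fry gave 0.011 for the same median of -0.081; the cause was not tested. Over 12 settings its camera adjusted p ran from 0.032 to 0.32. The labels do not say whether the replicate numbers pair the samples. Deviations from the group means of same-numbered libraries had a correlation of -0.02 across 12510 genes, so no signal shared by number was seen. With the block 4040 genes were higher and 4337 lower, and the cholesterol biosynthesis list passed camera (adjusted p = 0.033). All 77 genes of the naming rule kept their direction and their side of the threshold in the 887 results that the alternatives gave, and so did 499 of 504 results of the 45 genes named after their values were seen, the exceptions being mt-Co1 (3 results), Apoe without overexpression 1 and Lyz2 without control 2, which then passed. The rule picked nearly all of those 77 genes for large changes in these same libraries, so their agreement was close to fixed in advance. A setting in which a low gene was not tested gave no result. Several list medians moved by over 1.5 times: over 12 settings they ran from -0.10 to -0.045 for NF-kB target genes, -0.10 to -0.061 for NF-kB signalling components, -0.14 to -0.026 for mesenchymal and EMT genes, 0.044 to 0.22 for Wnt and Notch targets and -0.13 to -0.038 for p53 targets, and those of the stem cell markers, the proteasome and ubiquitin genes and the luminal epithelial genes (-0.18 to 0.66) changed sign. The 7 lists past camera stayed past it in all 12 settings. None did with an estimated correlation, which the few residual degrees of freedom make hard to pass. Of the methods for counts only limma-voom was run, on expected counts recovered from the CPM; DESeq2 was not run. Depth limits genes under 1 CPM, where 1 read is worth 0.046 to 0.063 CPM.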

Other observations

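The gene ontology terms, the YAP and TEAD list, and the tests of nuclear copies, the spread among mitochondrial mRNAs, neighbouring genes near 0, populations per group, scaling and the share of NF-kB target genes that rose were chosen only after the results they bear on had been seen. Those of adjacent pairs, thinned depth and nuclear respiratory chain genes were chosen after the patterns had been seen and before their own values were computed, although correlations of change between neighbouring genes along whole chromosomes had been looked at before the adjacent pairs were counted.

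Of 961 gene ontology terms tested, 4 were lower and 1 higher by camera with the preset correlation, and 0 passed with an estimated correlation (adjusted p = 0.99 for each of the 5). The latter form rests on 2 residual degrees of freedom and could hardly pass any of 961 terms, so it decides nothing here. Ribosome biogenesis was lower (47 of 79 genes fell and 9 rose, median log2 fold change -0.23, camera adjusted p = 0.014), as were tRNA aminoacylation (20 of 33 fell, 2 rose, median -0.26, adjusted p = 0.030), the cellular response to interferon gamma (20 of 29 fell, 4 rose, median -0.52, adjusted p = 0.014) and proton transport coupled to ATP hydrolysis (12 of 16 fell, 0 rose, median -0.27, adjusted p = 0.048). Regulation of microtubule cytoskeleton organization was higher (13 of 15 rose, 1 fell, median 0.37, adjusted p = 0.042).

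Cyr61 (402 ± 32.2 to 1242 ± 22.5 CPM, log2 fold change 1.63 ± 0.04), Ctgf (2.29 ± 0.12), Ankrd1 (1.29 ± 0.04) and Amotl2 (0.96 ± 0.04) rose together with Tead2, with Cyr61, Ankrd1 and Amotl2 named after their values were seen, and all of these but Tead2 are known transcriptional targets of YAP and TEAD. The hypothesis that such targets were higher as a group was tested on a 22-gene list. Of 20 tested members 12 rose and 5 fell, but these include the genes that prompted it. Without Cyr61, Ctgf, Ankrd1, Amotl2 and Tgfb2, 7 of 15 rose and 5 fell, with a median of 0.11. The camera p was 0.33 with the preset and 0.53 with an estimated correlation. The fry p was 0.0065 upward, but fry does not compare the list with other genes. A rise of the group beyond the named genes stays open.

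The mRNAs of the mitochondrial genome were lower with Mtss1 overexpression: 12 of 13 fell, with a median log2 fold change of -1.03, from -2.69 for mt-Cytb to -0.08 for mt-Co1, which did not pass (named after its values were seen, as were the rRNAs, it passed with limma-voom and without control 1 or control 2, adjusted p from 0.0047 to 0.73 over 12 settings). Adding the CPM of 14 nuclear copies left the median at -0.99 and the changes of the 13 mRNAs between -2.69 and -0.05. The median could hardly have moved, because many of these mRNAs have no annotated copy or one with few reads. However, the 3 mRNAs without an annotated copy fell as well (log2 fold changes -1.91, -0.99 and -0.76). For these, that argues against reads exchanged with annotated copies. A like loss of all mitochondrial RNA would lower the mRNAs alike, and the changes of mt-Co1 and mt-Cytb lay 2.61 apart (SE 0.07), which argues against it as the only cause; the mitochondrial rRNAs rose, mt-Rnr2 by 0.36 ± 0.04 and mt-Rnr1 by 1.22 ± 0.05, but whether poly(A) RNA was selected or rRNA depleted is not given in the sources used here, so their rise decides nothing. The nuclear genes of the respiratory chain had a median of 0.041 (SD 0.27 over 89 genes, 25 higher and 19 lower), so they did not share the fall. A lower level of these mRNAs in the overexpressing cells and a difference in how library preparation captured them both stay open, since the labels give the same protocol for all libraries without saying how RNA was selected, and no other measure of mitochondrial RNA was analysed here.

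The on and off pattern concerned 14 genes, found from their values and outside the naming rule except for Tead2, Epb41l3, Slco5a1 and Bend4, with at least 10 CPM in both libraries of a group and under 0.5 CPM in both of the other. Near 0 in the control were 13, Tead2, Epb41l3, Slco5a1, Bend4, Brinp3, Cpne8, Tiam1, Celf2, Zfp704, Tgfa, Hdac11, Tsnax and Eda, and near 0 with overexpression was Gm28438, a nuclear copy of mitochondrial DNA. Gm28438 aligns to mt-Nd3, which fell from 30.3 to 9.14 CPM, and it read 0.0012 CPM in overexpression 2, less than 1 read. Its values may therefore partly reflect how reads shared with mt-Nd3 were divided. A changed division alone would leave the sum of the 2 genes unchanged. The log2 fold change of that sum was -2.60, against -1.64 for mt-Nd3 by itself. This argues against a division between these 2 genes as the only cause. Loss of a stretch of chromosome that reaches the nearest tested genes would leave those near 0 too, and 1 of 28 was (3.57%; Pag1, named after its values were seen, beside Zfp704), which argues against such a loss for most of these genes and leaves changes at single genes untested, while a count of adjacent pairs (0, with a random median of 0) could not decide. Depth was higher in the control, so a lack of reads could not have produced the 13 genes near 0 there. With every library thinned to the shallowest 92.9% of the genes still met the definition, a result nearly fixed in advance for those 13. Sublines that differ apart from Mtss1 cannot be told apart from an effect of Mtss1, because each group holds 1 population.

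NF-kB target genes were lower and higher within the list, 16 and 11 of the 36 tested. The alternative scalings moved the median log2 fold change of all genes by at most 0.035 and left 11 members higher and 15 or 16 lower. The split thus did not depend on which of these scalings was used. Each of them sets the libraries to a common total or a common middle, so none could show a shift shared by most genes. Such a shift between the libraries stays open. A common fall of p65 output as the only cause would let few members rise, and 40.7% of those that changed rose (11 of 27). Such a fall alone leaves these rises unexplained. The count restates the pattern, however, and 48.2% of all genes past the threshold rose, so the share says little about p65 output. A loss at some targets with a gain at others stays open as a biological hypothesis, as does a change in other regulators of these genes, and no value here measures p65 protein or its binding.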
